A study of Mus musculus with 4 samples.

How the data were processed

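The samples were 4 RNA libraries from bone marrow myeloid progenitors of mice, 2 labelled Kras with wild-type Usp22 and 2 labelled Kras with Usp22 knocked out. Per the labels' protocols, cells positive for c-Kit and negative or low for lineage markers were sorted by flow cytometry from mice between 7 and 9 weeks old, RNA was extracted with Trizol, and strand-preserving poly(A) libraries were made with the Illumina TruSeq mRNA kit. The strain given is C57BL/6. The labels do not state the Kras allele, the deleted part of Usp22, the sex of the mice, or whether each library came from a separate animal. The p-values therefore measure only the spread between these samples, which may be technical.

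The deposited files hold raw counts, whole numbers of reads per gene symbol, with no normalization. The submitters' processing notes name FastQC, STAR, HTSeq and DESeq2 and the genome build mm10, with no versions. The gene annotation, the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. Genes with near-identical copies (ribosomal protein genes, globins, Oas1 and Gbp family members, Gapdh) are uncertain for that reason, as are overlapping genes. Each file lists 23337 symbols, many of them older names, which are kept here with the current name in brackets where it differs. Coordinates are those of GENCODE M21 on GRCm38, the assembly also called mm10: 20961 symbols matched it directly, 1903 through a RefSeq synonym, and 473 did not match.

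Total counts were 22351201 and 23117729 in wild-type replicates 1 and 2, and 21196387 and 14735224 in knockout replicates 1 and 2. A count of 3, taken as the floor of detection, corresponded to between 0.125 and 0.181 CPM (counts scaled to the size of the library, the usual unit), and covers counting error only. Of the symbols, 15724 had a count in at least 1 library. The default expression filter of edgeR 4.0.16 (filterByExpr, minimum count of 10) kept 12143 genes, and the genes left out held 0.0753% of all counts.

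The main test was edgeR's quasi-likelihood F-test (R 4.3.3) on the deposited counts with TMM scaling, 1 term for genotype, and Benjamini-Hochberg adjustment with a threshold of 0.05. Fold changes are knockout over wild type, CPM values are TMM-scaled, and standard errors (SE) are the absolute log2 fold change divided by the square root of F. With 2 libraries against 2, an exact permutation test of a single value cannot give a two-sided p below 0.333, so none is reported. Before the data were examined, 30 gene lists were fixed: the SAGA complex; PU.1-dependent myeloid genes; lineage transcription factors; primary granule genes; secondary and tertiary granule genes; monocyte and macrophage, dendritic cell and MHC class II, stem and multipotent progenitor, erythroid, megakaryocyte and platelet, basophil, mast cell and eosinophil, B and plasma cell, T and NK cell, and stromal and endothelial genes; S phase and G2 and M phase genes; interferon-stimulated genes; RAS and MAPK feedback genes; MYC targets and ribosome biogenesis; cytosolic ribosomal proteins; p53 targets; unfolded protein and integrated stress response; immediate early and heat shock; NF-kB and inflammatory; nuclear oxidative phosphorylation; glycolysis and hypoxia; cholesterol biosynthesis; mitochondrially encoded; replication-dependent histone; and sex-linked genes. The 28 with at least 5 tested members were tested against all other genes with camera (limma 3.58.1) at its preset inter-gene correlation of 0.01, adjusted over the lists, and the sex-linked genes were kept as values; none of the mitochondrially encoded genes could be tested. No list passed when camera estimated the correlation (lowest adjusted p = 0.644; 1 list at an unadjusted p under 0.05). With fry, which asks whether a list's genes move one way on balance and does not compare them with other genes, none passed either (lowest adjusted p = 0.0643; 6 lists at an unadjusted p under 0.05). Counts of list members refer to the adjustment over all genes unless stated otherwise.

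The genes named were chosen by a rule set in advance. It took Usp22, Kras and Spi1, then the 12 largest rises and 12 largest falls among genes that passed. Those had a mean of at least 1 CPM and no overlap between groups, leaving out predicted, unnamed and sex-linked genes. From each list it took up to 4 passing members with the smallest adjusted p. Other members are named only to show what a list did, and were chosen after their values were seen.

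Replicates differed by more than sampling noise: the chi-square statistic over its degrees of freedom was 30.8 between the wild-type and 47.0 between the knockout libraries. Each library was treated as a sample, although this excess does not separate animals from preparations. Alternatives set in advance were other scalings, filters and tests (DESeq2 1.42.0, limma-voom, robust quasi-likelihood), the replicate number as a block, a fold minimum, and leaving out each library in turn. Leaving out 1 library sets 1 sample against 2, so that the lone sample is assumed to vary like the other group. Added after the data were seen were a crossed pairing, a test without X and Y genes, thinning to the smallest library, and a test without the 20 most abundant genes.

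The tests were checked on counts simulated from the wild-type means, the library sizes and the fitted dispersions, with 200 changed genes. The edgeR test ran over 11854 genes. Of 50 genes each changed 1.5-fold, 2-fold, 4-fold and 8-fold, it recovered 2%, 30%, 94% and 96%, and 5 unchanged genes were called. In the measured libraries 2442 of 12143 genes were called. The adjustment depends on that share, so these recovery rates do not carry over to the main test. A simulated 1.5-fold rise of the G2 and M phase list, over 11857 genes, gave an adjusted p of 4.02e-58 with camera, 0.0695 with an estimated correlation and 0.0448 with fry, with no other list called. Each gene was drawn independently, so this check could not show false calls of lists whose genes vary together. In the measured libraries the estimated correlation was 0.58 for the G2 and M phase list. Figures were drawn with matplotlib 3.10.9.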

Results

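Gene expression was measured by RNA sequencing in myeloid progenitors sorted from the bone marrow of mice carrying the labelled Kras background, with Usp22 either intact (wild type, 2 libraries) or knocked out (2 libraries). Usp22 is a deubiquitinase of the SAGA coactivator complex. The comparison asks which transcripts differ when it is lost in these cells. The libraries, called wild type 1 and 2 and knockout 1 and 2 after their group and replicate, held between 14735224 and 23117729 counts, with knockout 2 the shallowest. S100a9, a neutrophil calcium-binding protein, was the most abundant transcript in each of the 4 libraries, at 4.88% and 6.10% of counts in the wild type and 4.01% and 3.82% in the knockout. By mean share over the libraries Ngp, S100a8, Ltf, Camp and Lcn2 came next (3.17%, 3.16%, 1.93%, 1.41% and 0.97%). These are also genes made late in neutrophil maturation. Whether their RNA came from progenitors or from more mature cells in the sort was not tested. The first principal component held 74.9% of the variance and separated the groups, with scores of -41.4 and -44.7 in the wild type and 21.9 and 64.2 in the knockout. Xist and the Y-linked genes set wild type 1 apart: it held 17674 Xist counts and no Ddx3y count, against at most 3 Xist and at least 840 Ddx3y counts in the other 3 libraries. The labels give no sex, but such counts are those of female cells in wild type 1 and of male cells in the other 3 libraries. The groups were therefore not balanced for sex. Of the comparisons made here, only that without wild type 1 sets libraries of the same sex against each other.

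The Usp22 transcript (chromosome 11, 61151785 to 61175055, minus strand) was lower in the knockout, as the labels name it. Its level was 98.5 and 92.3 CPM in the wild-type libraries and 25.7 and 15.5 CPM in the knockout libraries, a fall of 4.61-fold (log2 fold change -2.20, SE 0.25; edgeR quasi-likelihood adjusted p = 0.00756). Reads remained in both knockout libraries (616 and 257 counts), and the deleted exons are not given. Of the 22 tested members of the SAGA complex, Usp22 and Atxn7l1 fell and Eny2 and Kat2a, a cofactor of the deubiquitinase module and the acetyltransferase, rose (Eny2 0.68, SE 0.19; Kat2a 0.68, SE 0.19). The other 18 did not pass, and adjusted over the list alone the counts were 3 higher and 2 lower. As a list they did not pass against other genes (camera adjusted p = 0.545), and their median of -0.042 became 0.31 with total-count scaling, where 5 rose and 1 fell. The calls for Atxn7l1, Eny2 and Kat2a were each lost without wild type 1 or wild type 2. Those for Atxn7l1 and Kat2a were lost also without knockout 1, and those for Atxn7l1 and Eny2 also without knockout 2. None of the 3 held without the low-count filter, where the list had none higher and 1 lower. That for Atxn7l1 was lost also with total-count and upper-quartile scaling, and that for Kat2a also with a replicate block. Kras itself stood at 121.5 and 125.2 CPM in the wild type and 86.8 and 92.9 CPM in the knockout (log2 fold change -0.46, SE 0.16), which did not pass (edgeR adjusted p = 0.0735). Over the alternatives its adjusted p ranged from 0.0491, with DESeq2, the only setting that called it, to 0.613, with total-count scaling.

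Across the transcriptome, 2442 of 12143 genes changed, 1162 higher and 1280 lower in the knockout, and 1305 of them by at least 2-fold. Among the largest rises, Sh3tc2 (chromosome 18, 61953075 to 62024402), an endosomal adaptor, had no count in the wild type and 33.6 and 8.51 CPM in the knockout, at least 140.8-fold higher for the mean and 56.9-fold for knockout 2 alone, against a floor of 3 counts per wild-type library. The epithelial transcription factor Ehf rose (log2 fold change 3.74, SE 0.57), as did the tyrosine phosphatase Ptprr (3.86, SE 0.69), the serine protease Tmprss6 (0.124 to 2.10 CPM), Zcchc18 (3.01, SE 0.60) and Ncrna00086 (Smim10l2a; 3.22, SE 0.66). Several other large rises were carried mostly by knockout 2. The growth factor Igf2 stood at 1.33 CPM in knockout 1 and 51.6 CPM in knockout 2, and the embryonic globin Hbb-bh1 at 1.04 and 20.1 CPM. The lipid desaturase Scd1 stood at 1.29 and 7.60 CPM, and the lymphocyte receptor Crtam at 3.84 and 13.8 CPM. Sept4 (3.29, SE 0.86) and the erythroid carbonic anhydrase Car1 completed the 12, with Car1 at 3 counts in the wild type against 115 in the knockout (38.1-fold higher, 95% exact counting interval 12.7 to 187). Of these 12 calls, only those for Sh3tc2 and Ehf held without each library in turn. Those for Igf2, Hbb-bh1, Scd1, Sept4, Crtam, Car1, Zcchc18 and Ncrna00086 were lost without knockout 2, all but that for Crtam also without a wild-type library. With limma-voom the calls for Igf2, Hbb-bh1, Scd1, Crtam and Sept4 were lost, those for Igf2 and Hbb-bh1 also with robust quasi-likelihood and that for Igf2 also with a replicate block. Those for Ptprr and Tmprss6 were lost without either wild-type library.

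Among the largest falls, Lipg, the endothelial lipase, stood at 29.0 and 26.2 CPM in the wild type against 0 and 0.845 CPM in the knockout (log2 fold change -6.22, SE 0.77). The interferon-inducible genes Gbp1 (Gbp2b; 109 counts against 1, 110-fold higher in the wild type, 95% exact counting interval 19.3 to 4380) and Ifi202b (7.04 and 4.14 CPM against 0.250 and 0) were close to absent in the knockout. Tex15 fell (-4.09, SE 0.45), as did Nt5e, the ecto-nucleotidase CD73 (-3.67, SE 0.44), and the chaperone family member Hspa12a (-5.11, SE 0.63). The others were Rasgef1a (-4.58, SE 0.52), the prostaglandin receptor Ptgdr (-4.17, SE 0.65), the chemokine-like Prok2 (-3.54, SE 0.47), Cd8a (-3.93, SE 0.74), Dnahc6 (Dnah6; -3.78, SE 0.77) and Aldh3b2 (-3.70, SE 0.86). Of these 12 calls 8 held without each library in turn. The calls for Ptgdr and Dnahc6 were lost without wild type 2, Aldh3b2 without either wild-type library and with the DESeq2 Wald test, and Cd8a without wild type 1, wild type 2 or knockout 2. Scaling by total counts moved the median log2 fold change of all genes from 0.028 to 0.38, so the changes given here are relative to the median gene under TMM. List medians given with total-count scaling carry this shift, so a change of sign alone is no reversal against other genes. The split of changed genes went from 1162 higher (47.6%) and 1280 lower to 3229 higher (83.4%) and 644 lower, and upper-quartile scaling gave 1823 higher (62.2%) and 1108 lower. The count of changed genes was 1012 without wild type 1, 701 without wild type 2, 3824 without knockout 1 and 748 without knockout 2.

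**Figure D1:**
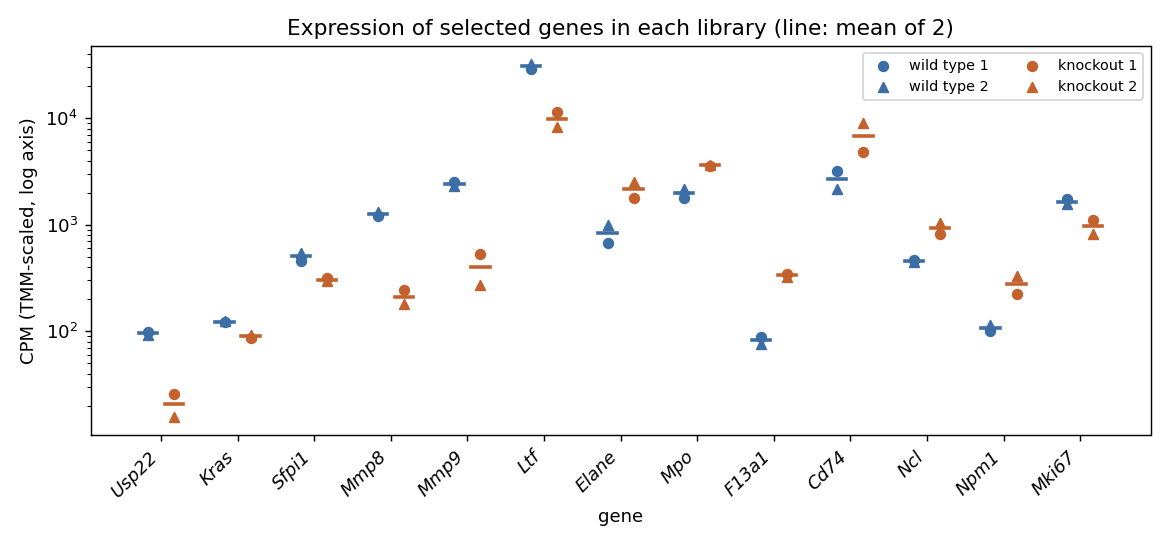
CPM (TMM-scaled, log axis) of 13 genes in each of the 4 libraries, with circles for replicate 1, triangles for replicate 2 and a line at the mean of each group. Usp22 lies at 92.3 and 98.5 CPM in the wild type and at 15.5 and 25.7 CPM in the knockout.

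Genes of the secondary and tertiary neutrophil granules, made late in neutrophil maturation, were lower in the knockout almost throughout. Of 22 tested, 21 fell and none rose, and adjusted over the list alone all 22 fell, with a median log2 fold change of -1.46. Mmp8, the neutrophil collagenase, went from 1220 and 1308 CPM to 244.9 and 178.4 CPM (-2.58, SE 0.21). The gelatinase Mmp9 fell likewise (-2.58, SE 0.32), as did the resistin-like Retnlg (-1.86, SE 0.18) and the glycoprotein Lrg1 (-1.75, SE 0.21). The abundant S100a9 and S100a8 lay at the other end, at -0.84 and -0.75, the latter not past the threshold over all genes and the former not with total-count or upper-quartile scaling or without wild type 2, knockout 1 or knockout 2. The list was lower than other genes by camera (adjusted p = 1.17e-27; adjusted p = 0.644 with an estimated correlation).

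Of the primary granule genes, made earlier, more rose than fell. Of 18 tested, 9 rose, 3 fell and 6 did not pass, with 11 higher and 4 lower adjusted over the list alone and a median log2 fold change of 0.69. The rises included the cathepsins Ctsg (1.40, SE 0.20) and Ctsc (1.74, SE 0.26), the cystatin Cst7 (1.71, SE 0.22), elastase Elane (1.37) and myeloperoxidase Mpo (0.86). Lysozyme Lyz2, which is also made by mature neutrophils and macrophages, fell (-1.27, SE 0.20), as did Mgst1 and Cd63. The list was higher by camera (adjusted p = 0.00516; adjusted p = 0.775 with an estimated correlation). Its members higher numbered 4 without wild type 1 and 3 without knockout 2, and the list no longer passed without wild type 1. The calls for Elane and Mpo were lost without knockout 2 and that for Mpo also without wild type 1. Those for Mgst1 and Cd63 were lost without wild type 2, and that for Cd63 also without each other library and with total-count scaling.

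Sfpi1 (Spi1, encoding the myeloid transcription factor PU.1; chromosome 2, 91082390 to 91115756) stood at 460 and 548 CPM in the wild type and 317 and 294 CPM in the knockout (log2 fold change -0.72, SE 0.17; edgeR adjusted p = 0.0276). Of 38 tested genes that depend on PU.1 in myeloid cells, 18 fell and 6 rose (20 lower and 8 higher adjusted over the list alone), with a median of -0.57. The interleukin 1 receptor antagonist Il1rn (-2.54, SE 0.20), the NADPH oxidase subunit Cybb (-1.52, SE 0.21) and the integrin chain Itgb2 (-1.24, SE 0.18) fell, while Klf4 (1.48, SE 0.18), Ctss, Elane, Cd68, Csf1r and Mpo, genes of monocytes or of primary granules, rose. The receptor gene Csf3r (-1.41) and the integrin chain gene Itgam (-1.69) also fell. The calls for Cd68 and Csf1r were lost without wild type 2, and that for Csf1r also without knockout 2. The list was lower by camera (adjusted p = 0.00139; adjusted p = 0.644 with an estimated correlation), and 13 of its members also stand in other lists. The Sfpi1 call was lost with total-count scaling (-0.37; edgeR adjusted p = 0.116, in a range from 0.000709 to 0.184 over all alternatives) and without wild type 1, wild type 2 or knockout 2. The higher members numbered 3 without knockout 2, and the lower members 10 with total-count scaling and 12, 6 and 7 without wild type 1, wild type 2 and knockout 2, respectively.

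Among 26 lineage transcription factors, 7 fell and 2 rose (10 lower and 3 higher adjusted over the list alone). Nfe2 (-1.49, SE 0.20) and Cebpe (-1.33, SE 0.19), the latter needed for secondary granules, fell together with Cebpd, Erg, Ikzf1, Fli1 and Sfpi1, whereas Klf4, a monocyte factor, and the erythroid factor Klf1 rose. Irf8 and Cebpa, factors of the monocyte and granulocyte branches, had values of 0.52 and 0.61 that did not pass. As a list they did not pass against other genes (camera adjusted p = 0.132), and their median of -0.27 became 0.084 with total-count scaling, where 5 rose and 4 fell. The lower members numbered 3 without wild type 1 and 2 without wild type 2 or knockout 2. The calls for Erg, Ikzf1 and Fli1 were lost without each of these (for Ikzf1 and Fli1 also with total-count scaling), that for Cebpd without wild type 2 or knockout 2, and the Klf1 call, at under 1 CPM, without any of the 4 libraries.

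Genes of dendritic cells and MHC class II were higher in the knockout, and monocyte genes went both ways with more rises than falls. Of 28 monocyte and macrophage genes, 8 rose and 2 fell (10 and 3 adjusted over the list alone), led by the factor XIII subunit F13a1, at 88.95 and 76.57 CPM in the wild type against 346.3 and 325.8 CPM in the knockout (2.02, SE 0.17), and by Ly86 (1.66, SE 0.26), Klf4 and Ms4a6c (1.19, SE 0.20). Cd14 and Fcgr4 fell, though neither call held with total-count scaling or without wild type 2. The monocyte median of 0.41 became 0.035 without knockout 2, and by library the list lay at 0.0355 in knockout 1, below 0.141 in wild type 1, and at 0.569 in knockout 2. Macrophage complement genes C1qa, C1qb and C1qc, near 2 CPM, had values of -0.40, -0.34 and 0.16 that did not pass. Of 20 dendritic cell and MHC class II genes, 11 rose and none fell (13 and 0 adjusted over the list alone), with all 20 fold changes above 0 and a median of 1.06. The median was 0.62 without knockout 2, 3 of the 20 fold changes were negative without wild type 2, and 5 members rose with a replicate block. Siglech, a plasmacytoid dendritic cell lectin (2.30, SE 0.23), the plasmacytoid transcription factor Tcf4 (1.19, SE 0.20), the receptor Flt3 (1.05, SE 0.20) and Batf3 (1.06, SE 0.25) rose, as did the MHC class II genes H2-Aa, H2-Ab1, H2-Eb1 and Cd74. By camera the adjusted p was 0.00854 for the monocyte and 4.7e-07 for the dendritic list (adjusted p = 0.775 with an estimated correlation for each). The dendritic members higher numbered 1 without wild type 2 and 3 without knockout 2, the library in which markers of T and NK cells also stood highest. The monocyte members higher numbered 4 without wild type 2, with the monocyte list no longer passing camera without wild type 2 or knockout 2. The calls for Ms4a6c, Tcf4, Flt3, Batf3 and the MHC class II genes were lost without wild type 2, those for Batf3 and the MHC class II genes also without knockout 2, and that for Batf3 also without wild type 1.

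**Figure D2:**
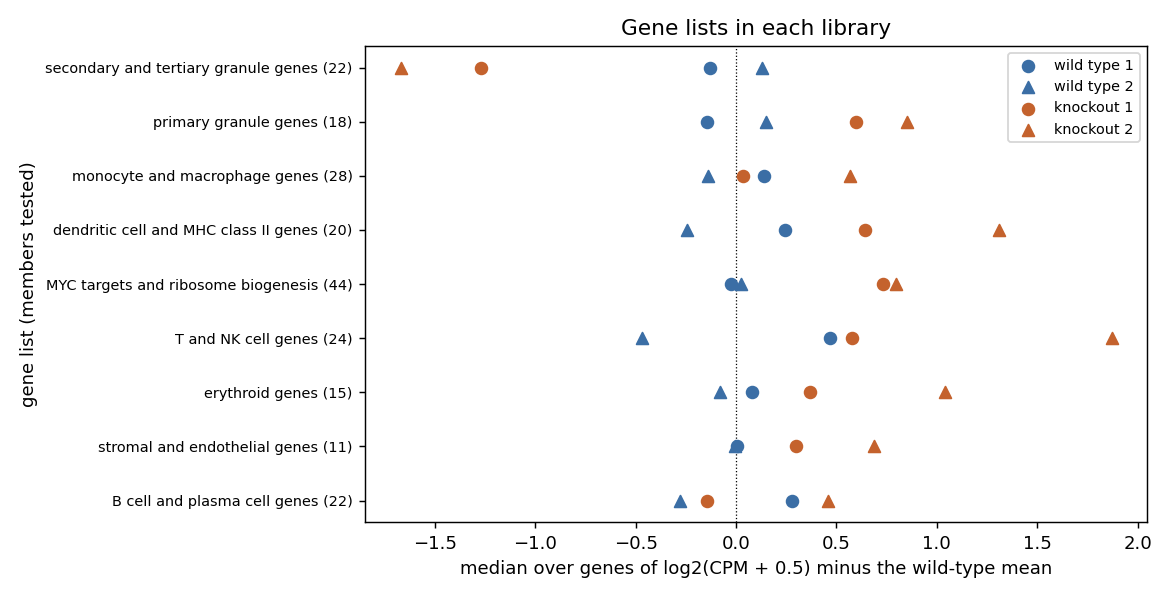
Median over the members of 9 gene lists of log2(CPM + 0.5) minus the wild-type mean, in each of the 4 libraries (number of members in brackets). Late granule genes lie at -1.27 and -1.67 in the knockout libraries, and the T and NK cell list lies at 0.58 in knockout 1 and 1.87 in knockout 2.

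Genes for making ribosomes were higher in the knockout. Of 44 MYC targets and ribosome biogenesis genes, 32 rose and 1 fell (37 and 1 adjusted over the list alone), with a median of 0.78. The nucleolar proteins Npm1 (1.37, SE 0.22) and Nop16 (1.21, SE 0.19), the folate carrier Slc19a1 (1.53, SE 0.22) and the spermidine synthase Srm (1.14, SE 0.20) led the list, Myc itself rose (0.76, SE 0.17), and the hexokinase gene Hk2 fell. Of 73 cytosolic ribosomal protein genes, 40 rose and none fell (48 and 0 adjusted over the list alone), with a median of 0.98 and examples such as Rpl14 (1.22, SE 0.23), Rps2 (1.06, SE 0.21), Rpl13a (1.20, SE 0.24) and Rplp1 (1.29, SE 0.25). Both lists were higher by camera (adjusted p = 4.11e-13 for each; with an estimated correlation adjusted p = 0.644 for biogenesis and 0.775 for ribosomal proteins). Biogenesis members higher numbered 6, 4 and 12 without wild type 1, wild type 2 and knockout 2, and ribosomal protein members 1, 8 and 8. The Myc call was lost without either wild-type library, with the calls for the 4 ribosomal protein genes and Srm lost without wild type 1, and that for Rps2 lost also without wild type 2. The Hk2 call was lost without wild type 1, wild type 2 or knockout 2 and with total-count scaling. Ribosomal protein genes have many processed copies, and some stood under 1 CPM (Rps23 at 0.646 CPM in the wild type), so their levels are uncertain.

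Among cell cycle genes, those of G2 and M phase leaned lower with TMM scaling, and the S phase list did not pass. No test compared the lists with each other. For all 12143 tested genes, 1162 rose and 1280 fell. Of 51 G2 and M phase genes, 7 fell and none rose over all genes, none passed adjusted over the list alone, and 48 had negative fold changes, with a median of -0.42. Hjurp (-1.19, SE 0.30), Cenpf (-0.86, SE 0.22), Dlgap5 (-0.72, SE 0.17) and Smc4 (-0.66, SE 0.17), genes of centromeres, spindles and chromosome condensation, fell, and the proliferation marker Mki67 went from 1652 to 963.6 CPM. Of 41 S phase genes, Ung (0.88, SE 0.20), Msh2 (0.72, SE 0.18) and Hells (0.63, SE 0.16) rose and none fell, none passed adjusted over the list alone, and the median was 0.10. The G2 and M list was lower by camera (adjusted p = 1.0e-05; adjusted p = 0.775 with an estimated correlation), and the S phase list did not pass (camera adjusted p = 0.497). With total-count scaling no G2 and M gene passed (median -0.070) while 15 S phase genes rose. The G2 and M list was then still lower than other genes by camera (adjusted p = 0.000456). With upper-quartile scaling 4 G2 and M genes fell, and with the DESeq2 Wald test 17 fell. The count of lower G2 and M genes was 0 without either wild-type library, 27 without knockout 1 and 1 without knockout 2. The Hjurp call was lost without either wild-type library, and the other calls named here were lost without wild type 1, wild type 2 or knockout 2.

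Interferon-stimulated genes were mixed, with a part of them clearly lower. Of 51 tested, 13 fell and 3 rose, also adjusted over the list alone. The 2'-5' oligoadenylate synthetase genes Oas1g (9.56 to 0.939 CPM; -3.36, SE 0.42) and Oas3 (-1.80, SE 0.23) and the receptor transporter Rtp4 (-1.80, SE 0.22) fell together with Oas2, Oas1a, Rsad2 and Ddx58, whereas Gbp3 (1.80, SE 0.23), Psmb8 and Bst2 rose. Isg15, Mx1 and Stat1 had values of -0.16, -0.17 and -0.42 that did not pass. The list was lower by camera (adjusted p = 0.0237, and 0.791 with an estimated correlation). Its median of -0.20 became 0.14 with total-count scaling, where 8 fell and 5 rose. The median of all genes then stood at 0.38, and the list was still lower than other genes by camera (adjusted p = 0.0138). The median of the list was -0.028 without wild type 1, -0.052 without knockout 1, -0.40 without wild type 2 and -0.46 without knockout 2. Its lower members numbered 6 without wild type 1 and its higher members 8 without knockout 1 and 1 without each other library, and the list no longer passed without wild type 1 or knockout 1. The Oas1a call was lost without wild type 1, the Rsad2 call without wild type 1, knockout 1 or knockout 2 and with total-count scaling, and those for Psmb8 and Bst2 without wild type 1, wild type 2 or knockout 2.

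Genes that RAS and MAPK signalling induces as feedback did not move together. Of 22 tested, the phosphatase Dusp6 (-1.11, SE 0.16), the urokinase receptor Plaur (-1.85, SE 0.27), Phlda1 (-1.42, SE 0.31) and Ier3 fell and Myc rose (4 lower and 2 higher adjusted over the list alone), and 17 did not pass, among them Spry2 (0.030) and Etv5 (-0.0091). The median of 0.011 and the mean of -0.040 differed in sign, and the list did not pass against other genes (camera adjusted p = 0.572). The calls for Phlda1 and Ier3 were lost without wild type 2 or knockout 2, that for Myc without either wild-type library, and 5 members were higher without knockout 1. With total-count scaling 3 rose and 3 fell (median 0.36), and the Ier3 call was lost.

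Markers of other cell types were examined as lists. The sorting gate, c-Kit positive and lineage negative or low, is meant to remove mature cells that carry lineage markers. Which markers were used and how pure the sort was are not stated here, for neutrophils as for the other cell types. Of 24 T and NK cell genes, Klrb1c (2.74, SE 0.73), Cd2 (2.79, SE 0.73), Klrd1 (1.86, SE 0.39) and Lck rose and Cd8a fell (4 and 1 adjusted over the list alone as well; median 1.44; camera adjusted p = 0.00445; adjusted p = 0.775 with an estimated correlation). Without knockout 2 or without wild type 2 none passed in either direction, while 8 rose without wild type 1, 15 without knockout 1, 10 with total-count and 8 with upper-quartile scaling. Only 1 rose with limma-voom or with a replicate block, and 7 with the DESeq2 Wald test. The Klrb1c call was lost with the DESeq2 Wald test, limma-voom, robust quasi-likelihood and the replicate block, and the Cd2 call with limma-voom and the block. The list no longer passed camera without knockout 2 or with total-count scaling (adjusted p = 0.146, in a range from 9.11e-07 to 0.775 over its alternatives). Of 15 erythroid genes 5 rose and none fell (6 and 0 adjusted over the list alone; camera adjusted p = 0.0579), among them Tspan33 (1.17, SE 0.28), the spectrin Spnb1 (Sptb; 3 counts in the wild type against 42, 13.9-fold higher, 95% exact counting interval 4.44 to 70.1), Klf1 and Car1. No erythroid gene rose without wild type 2 or knockout 2, while 2 rose without wild type 1 and 11 without knockout 1. With no low-count filter 2 rose, and with limma-voom, a replicate block or thinned counts 3. The Spnb1 call was lost with no filter and with limma-voom, and the Klf1 call with no filter, the DESeq2 Wald test, a replicate block and thinned counts. Of 17 basophil, mast cell and eosinophil genes 4 fell and 1 rose (5 and 1 adjusted over the list alone; camera adjusted p = 0.0113; adjusted p = 0.644 with an estimated correlation): the histidine decarboxylase Hdc (-1.40, SE 0.19), Lmo4 (-1.16, SE 0.17), Prss34 (-1.37, SE 0.23) and Fcer1a fell, and Siglec5 (Siglecf; 0.87, SE 0.21) rose. The Siglec5 call was lost without any 1 of the 4 libraries, the Fcer1a call without wild type 1, wild type 2 or knockout 2, and the list's pass without wild type 2 or knockout 1. Of 22 B and plasma cell genes, Fcrla (2.79, SE 0.30) and the immunoglobulin joining chain Igj (Jchain; 1.88, SE 0.35) rose, also adjusted over the list alone, while Cd19 and Cd79a had values of -0.79 and -0.40 that did not pass (camera adjusted p = 0.143). The higher B and plasma cell members numbered 6 without knockout 1, 7 with total-count and 4 with upper-quartile scaling, and their median of 0.13 became -0.22 without knockout 2.

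Megakaryocyte, stromal and stem cell lists did not pass against other genes by camera (adjusted p = 0.309, 0.154 and 0.335). Of 16 megakaryocyte genes, Itgb3 (-1.13, SE 0.18), Thbs1 (-1.63, SE 0.28) and Gp1bb (-1.14, SE 0.31) fell and Vwf (1.17, SE 0.32) rose, also adjusted over the list alone. Of 11 stromal and endothelial genes, Pecam1 (0.80, SE 0.18) rose and Vcam1 (-0.67, SE 0.18) fell, also adjusted over the list alone. Of 24 stem and multipotent progenitor genes, Hmga2 (1.89, SE 0.40), Flt3 and Cd34 rose and Satb1 (-0.87, SE 0.16) and Gcnt2 (-0.81, SE 0.18) fell (5 and 2 adjusted over the list alone), while Kit, the gene of the sorting marker, had a value of 0.30 that did not pass. Of these calls, those for Hmga2, Gcnt2, Gp1bb, Cd34 and Vcam1 were lost without wild type 1, wild type 2 or knockout 2 (Cd34 and Vcam1 also without knockout 1, and Gcnt2, Gp1bb and Vcam1 also with total-count scaling). Those for Satb1 and Pecam1 were lost without either wild-type library, that for Flt3 without wild type 2, that for Vwf without wild type 2 or knockout 2 and with a replicate block, and that for Thbs1 without knockout 2. The Gp1bb call was lost also with a replicate block and with thinned counts, and the Vcam1 call with upper-quartile scaling and thinned counts. That for Cd34 was lost also with scaling by DESeq2 size factors. With total-count scaling 3 stromal members were higher and none lower. Without knockout 1, 9 stromal members were higher, and of the megakaryocyte genes 5 were higher and 4 lower, with the median going from -0.47 to 0.39 (0.10 without wild type 2). Of the stem and progenitor genes, 8 were higher and 1 lower with total-count scaling and 7 and 2 with upper-quartile scaling.

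**Figure D3:**
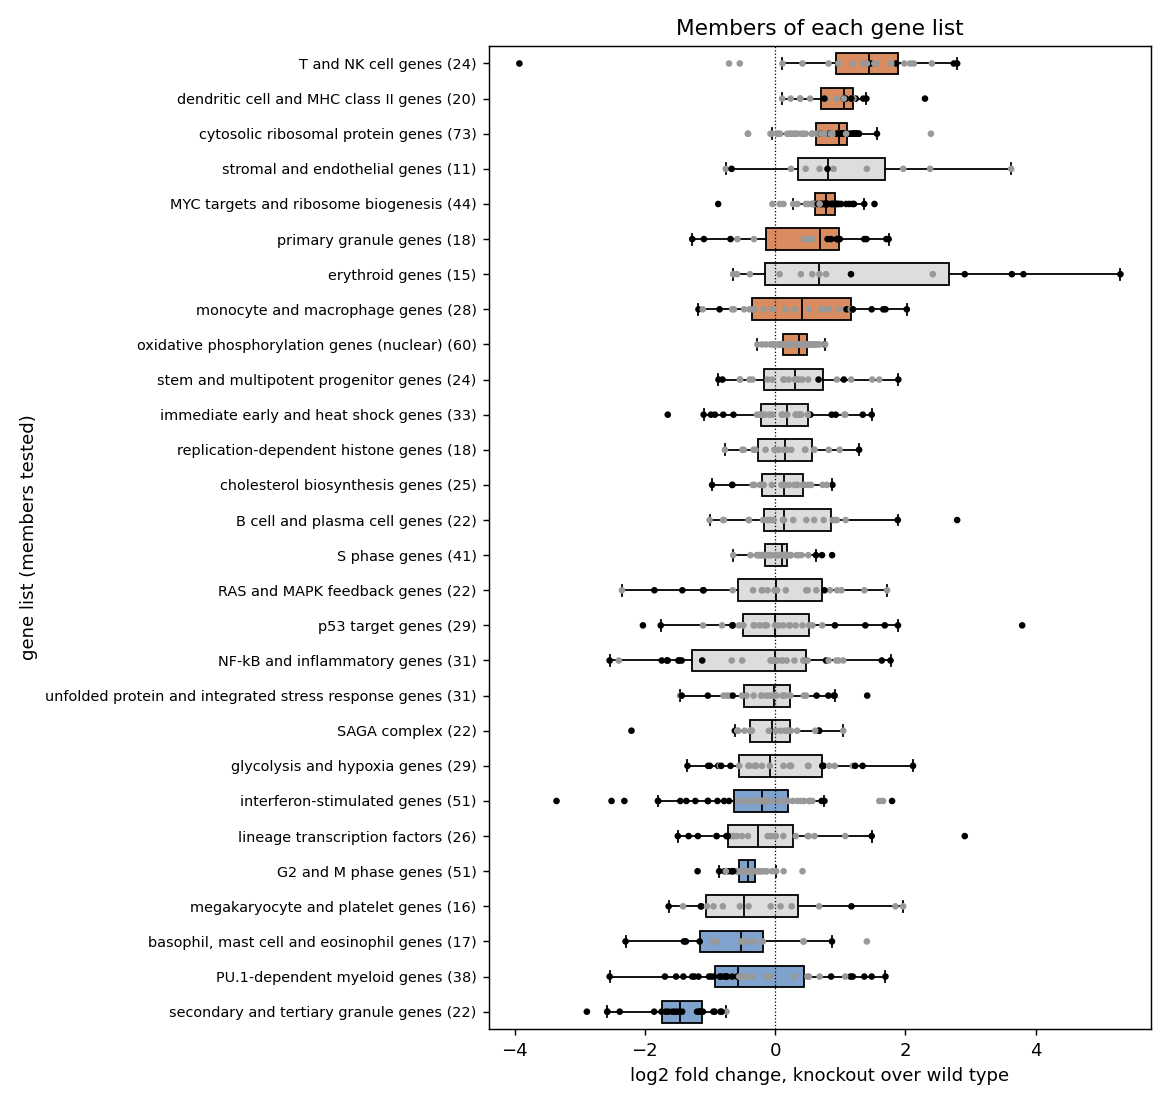
Log2 fold change of the tested members of 28 gene lists (number in brackets), knockout over wild type, with black points for genes that passed over all genes, grey points for others, and boxes from the lower to the upper quartile with a line at the median and whiskers to the furthest point within 1.5 box lengths. Boxes are orange (7 lists) or blue (5 lists) where camera found the list higher or lower with its preset correlation, and grey otherwise. With total-count scaling the median of the interferon-stimulated list goes from -0.20 to 0.14, and that of all genes from 0.028 to 0.38.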

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

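The crossed pairing, the omission of X and Y genes, the thinning and the omission of the 20 most abundant genes were chosen after the data were seen. With total-count scaling 3873 genes changed, 3229 higher and 644 lower, and 1806 of the 2442 calls were kept. With upper-quartile scaling 1823 were higher, and with a minimum of 2-fold 1305 changed, 633 higher and 672 lower. Pairing the replicates crosswise gave 1777 higher genes. Leaving out 1 library, which sets a lone sample against 2 and assumes that it varies like the other group, gave between 701 and 3824 changed genes, between 171 and 1803 higher and between 521 and 2021 lower. In none of these settings did a gene called in the main test change sign. The settings reuse the libraries that gave the calls, so a change of sign was unlikely from the start. Of 119 named genes that passed, 52 passed without each library in turn and 94 in each of the other settings in which the gene was tested. Among lists, camera's adjusted p for T and NK cell genes was 0.146 with total-count scaling. With an estimated correlation it was 0.644 for the late granule, PU.1, ribosome biogenesis and basophil lists, 0.775 for the primary granule, monocyte, dendritic, ribosomal protein, G2 and M and T and NK lists, and 0.791 for the interferon and oxidative phosphorylation lists. Adjusted p from fry, which tests a list against no change and not against other genes, was 0.0643 for the PU.1 and biogenesis, 0.0843 for the basophil, 0.0938 for the late granule, 0.252 for the ribosomal protein and G2 and M, 0.338 for the dendritic, 0.348 for the primary granule and monocyte, 0.381 for the oxidative phosphorylation, 0.465 for the T and NK and 0.479 for the interferon list. Leaving out 1 library, camera's adjusted p ranged from 9.11e-07 to 0.180 for T and NK, 0.0101 to 0.146 for basophil, 1.84e-06 to 0.869 for interferon, 0.00075 to 0.0738 for monocyte, 5.19e-06 to 0.119 for oxidative phosphorylation and 8.2e-05 to 0.117 for primary granule genes. Lists that passed only in an alternative were the erythroid (4 settings besides those without wild type 1, wild type 2 or knockout 1), stromal (without wild type 1, wild type 2 or knockout 1), B cell (without wild type 1 or knockout 1), and NF-kB and megakaryocyte lists (without knockout 2).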

Other observations

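Genes of sugar metabolism and hypoxia went both ways. Of 29 tested, 5 rose and 6 fell (5 and 7 adjusted over the list alone): Ddit4, an inhibitor of mTORC1 signalling (log2 fold change 2.12, SE 0.25), and the pyruvate dehydrogenase kinase Pdk1 (1.34, SE 0.19) rose, whereas the lactate exporter Slc16a3 (-1.34, SE 0.20) and Mxi1 (-1.03, SE 0.17) fell. The median of -0.082 and the mean of 0.062 differed in sign (camera adjusted p = 0.834). Of 31 unfolded protein and integrated stress response genes, 5 rose and 3 fell (5 and 4 adjusted over the list alone). The serine synthesis enzyme Phgdh (1.41, SE 0.19), Shmt2 (0.90, SE 0.16) and the amino acid transporter Slc7a5 (0.91, SE 0.18) rose, and asparagine synthetase Asns fell (-1.43, SE 0.20). The median of -0.014 lay against a camera direction of higher (adjusted p = 0.884). Of 60 nuclear oxidative phosphorylation genes, 1 rose (Ndufa10, 0.76, SE 0.17) and none fell, with none adjusted over the list alone and a median of 0.36. That list was higher by camera (adjusted p = 0.00112; adjusted p = 0.791 with an estimated correlation), but not without wild type 1 or knockout 2, and 37 of its genes rose with total-count scaling, 11 with upper-quartile scaling and 18 without knockout 1. Of 25 cholesterol genes, Dhcr7 rose and Hsd17b7, Ldlr and Sc4mol (Msmo1) fell, also adjusted over the list alone (camera adjusted p = 0.720). With total-count scaling 7 cholesterol genes rose and none fell, and of the 4 calls none held without either wild-type library. None of the 15 mitochondrially encoded genes was tested. The medians of the hypoxia and stress lists became positive with total-count scaling (0.27 and 0.33), where 9 rose and 2 fell, and 9 rose and 1 fell. The Ndufa10 call was lost without wild type 1, wild type 2 or knockout 2, those for Shmt2 and Slc7a5 without either wild-type library and that for Mxi1 without wild type 2. Without wild type 1 the hypoxia list held 2 higher and 2 lower genes and the stress list 1 and 1; without wild type 2 these were 2 and 1, and 1 and 1, and without knockout 2, 2 and 3, and 3 and 1. Without knockout 1 the stress list held 6 lower genes and the cholesterol list 4 higher.

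Inflammatory genes were mixed, with more falls than rises. Of 31 NF-kB and inflammatory genes, 8 fell and 3 rose (10 and 3 adjusted over the list alone; camera adjusted p = 0.143). The lectin receptors Clec4d (-1.66) and Clec4e (-1.49) fell with Il1rn, and the chemokine Ccl9 (1.64, SE 0.20) rose. The median of -0.0023 became 0.34 with total-count scaling. Of 33 immediate early and heat shock genes, 5 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.565), with Klf4 and Hspe1 higher and Zfp36 (-0.92) and Klf2 (-0.98) lower. Of 29 p53 targets, 5 rose and 4 fell (7 and 4 adjusted over the list alone; camera adjusted p = 0.974), with Zmat3 (1.68), Pmaip1 (1.39) and 9030617O03Rik (Dglucy) higher and Fas (-1.76) lower, and a median of -0.0016 against a mean of 0.11. Of 18 histone genes, Hist1h1c rose (1.29, SE 0.17), also adjusted over the list alone (camera adjusted p = 0.470). The p53 median became 0.35 with total-count scaling, where 8 rose and 2 fell (7 and 2 with upper-quartile scaling), and 11 immediate early and heat shock genes were then higher and 3 lower (median 0.53 against 0.19). Higher and lower p53 genes numbered 1 and 1 without wild type 1, 0 and 0 without wild type 2 and 0 and 1 without knockout 2, and the Zmat3, Pmaip1, 9030617O03Rik and Fas calls were lost without wild type 2 (Zmat3 and 9030617O03Rik also without wild type 1 or knockout 2, Pmaip1 also without knockout 2). Immediate early and heat shock genes numbered 1 and 4 without wild type 1, 2 and 1 without wild type 2, and 1 and 1 without knockout 2, the Hspe1 call being lost without wild type 1 or knockout 2 and those for Zfp36 and Klf2 without wild type 2 or knockout 2. Higher NF-kB members numbered 2 without wild type 1, 1 without wild type 2 or knockout 2 and 6 without knockout 1.

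Chosen only after the result was seen were the tests of the other cell types, of the G2 and M genes and of the most abundant genes for the granule pattern, and, for the near-absent genes, the tests of neighbouring genes and of the interferon list and the bound for the Usp22 segment. The late granule genes were lower by a median of -1.46. A few abundant genes setting the library sizes could be the cause, and the comparison of scalings cannot decide this. The late granule median was -1.46 with TMM (interquartile range 0.61) and -1.11 with total-count scaling. The step between them matched the 0.35 shift in the median of all genes, and is no evidence on its own. With the 20 most abundant genes left out, all 13 late granule genes still tested fell (median -1.55). This argues against that explanation for these 13 genes. A lower share of neutrophil-lineage cells would raise the markers of other cell types alike and lower primary granule genes too. Of 18 primary granule genes 9 rose and 3 fell (median 0.69). Medians of other cell types had both signs, with 1.44 for T and NK and 1.06 for dendritic genes against -0.52 for basophil and -0.47 for megakaryocyte genes. A lower share alone would not give these signs. It stays open all the same, because replicates also differed. The medians of 7 lists of other lineages spread over 1.67 between the groups, 1.18 between the wild-type and 1.52 between the knockout replicates. A shift toward earlier stages within the neutrophil lineage cannot be told apart from a change within cells, because each library averages over its cells. The G2 and M median was -0.42 under TMM and -0.070 with total-count scaling (interquartile range 0.25). That step also matched the shift of all genes. Against other genes the G2 and M list was lower by camera with both scalings (adjusted p = 1.0e-05 and 0.000456). With TMM and an estimated correlation it did not pass (camera adjusted p = 0.775). A lower expression of the late granule genes per cell in the knockout may also hold, and is untested.

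Ribosomal protein genes and ribosome biogenesis genes were higher by medians of 0.98 and 0.78. The ribosomal protein genes are shorter than others (median exonic length 1840 against 4431), but after a length trend fitted to other genes was removed their median was 0.84 (bootstrap 95% interval 0.73 to 0.94), and after a GC trend 0.93 (0.86 to 1.01). For the biogenesis genes the medians were 0.70 (0.63 to 0.82) and 0.75 (0.65 to 0.80), so that neither fitted trend accounted for the whole rise of either list in these libraries. The intervals resample the genes of a list with the trend held fixed, and hold no spread between libraries. Reads shared with processed copies of ribosomal protein genes were not tested and stay open. So does a difference that goes with the Usp22 genotype, which is a hypothesis here.

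There were 44 genes close to absent in 1 group (a log2 fold change of at least 3, with a mean under 0.5 CPM in that group and at least 1 CPM in the other), 28 of them lower in the knockout, such as Lipg, Gbp1 and Ifi202b. A passenger segment around the targeted Usp22 locus was argued against as the carrier of these genes, since 0 of the 44 lay within 10 Mb of Usp22, 43 lay on other chromosomes and the last, Sept4, lay 26.4 Mb away. Lower interferon signalling stays open for Ifi202b and Gbp1: the largest fall among interferon-stimulated genes, that of Oas1g, was smaller than the smaller of their falls by 1.88 (SE 0.90), but both were picked as large falls and Gbp1 lies under the floor in the knockout, while 13 interferon-stimulated genes fell. Segments of another strain elsewhere in the genome also stay open, as 4 of the 44 had another within 2 Mb against a median of 5 in 2000 random draws (5th to 95th percentile 0 to 11; permutation p = 0.764). An effect of the lost Usp22 on these genes is untested.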
